A study of Homo sapiens with 8 samples.

How the data were processed

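RNA was measured in 4 libraries of cord-blood CD34+ HSPCs, 2 with a hairpin against EGR1 and 2 with the Ren control hairpin, and chromatin bound by EGR1 in 3 ChIP samples with 1 input sample. Per the labels' protocols, RNA libraries were made with a stranded mRNA kit and ChIP used an EGR1 antibody of Santa Cruz, and the input sample is labelled with that antibody as well. Per the submitters' processing notes, bcl2fastq, TopHat, BWA, SAMtools and MACS2 were used with the hg19 build. No versions are given there, and the counting tool for RNA is not given in the sources used here. How the libraries were scaled and which low genes were removed is likewise not given in the sources used here.

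The RNA table holds CPM per library, as the authors deposited them. The columns sum to between 0.9921 and 1.009 times the nominal total over the listed genes, so the deposited CPM carry a scaling by the authors other than the plain column total. All CPM values were whole multiples of a single step per library within a tolerance of 0.1 steps (100% of values), which gives 39.94 to 42.09 M reads in the listed genes. The scaled library sizes that the steps give, 40.25 to 42.3 M, include the authors' scaling and are not read totals. Only 26 to 55 values per library lie within 20 steps, so these reads were used in an alternative and not in the main test. At this depth the counting error of a log2 ratio within a number had a median of 0.0522 over genes, and of 0.187 over the 1451 genes with a mean under 5 CPM. It covers counting error only. The table also holds a log2 fold change, a mean log2 CPM, a likelihood ratio score, a p-value with its FDR and a call per gene, all made by the authors with a tool that is not named in the file headers. The authors' call equals an FDR under 0.05. Where the mean of the same-numbered ratios and the ratio of group means differed, the fold change mostly lay off the latter and towards the former. Which of them it lay closer to was not tested. Of 175 genes with a mean of at least 5 CPM for which the 2 differ by over 0.1 on the log2 scale, 168 lay over 0.02 from the ratio of group means, and those 168 lay on the side of the mean of the same-numbered ratios. The peak list holds, per the file headers, hg19 positions, a score, a fold enrichment (a ratio of ChIP over input), −log10 p and −log10 q from the authors' peak caller, and a summit offset. The deposited score equals 10 times the −log10 q rounded down. Peak names run up to 306843 while 32753 peaks are listed (10.7%), so a selection was made that is not stated in the sources used here, and peaks were not called on pooled samples going by their names.

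Gene symbols were used as the file gives them. Members of the fixed lists were matched by symbol, or through synonyms in a RefSeq table of another build (GRCh38.p14), of which no coordinate was used. Of the 12677 genes, 38 were left out because they are sex-linked markers or immune genes that vary between people, which left 12639. The planned minimum of a mean of 1 CPM removed no gene, since the lowest mean was 1.08 CPM. Values were taken as log2(CPM + 1), which understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, on the 2 shEGR1 against the 2 shRen libraries without further covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 32 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 31 lists with at least 5 tested members. A fold change within a number is the difference of the 2 libraries with that number, and has no replicate.

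The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named EGR1, then 24 genes that passed with groups that did not overlap, filled up by the smallest p among genes with non-overlapping groups and a mean of at least 2 CPM in the higher group where too few passed (0 passed), then 4 members with the largest absolute fold change of each list that camera called and 2 members of each other list, and the 10 peaks of highest score. Genes named outside the rule are said to be chosen after their values were seen. The main test and camera were tested on simulated data made from the real means of each replicate number, with 200 changed genes in each of 10 runs over 12639 genes. Noise was drawn independently for each gene, with the spread that the fit with the number as a term assumes. With no term for the number, 0% of genes changed by 0.25, 0.5 or 1 on the log2 scale were recovered. With the number as a term, 52.7% of genes changed by 0.25 were recovered, 95.1% of those changed by 0.5 and 100% of those changed by 1, and 4.51% of calls were false. A mean of 0.2 lists per run was called by chance without the term and 0 with it. The simulation thus met the assumptions of the fit with the term, and its rates do not give the error rate on the real data. Genes of a list were independent in it, whereas the estimated correlation was 0.95 for the real ribosomal protein list in the fit without the term.

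The replicate numbers are shared by both groups, but neither the labels nor the series description ties a number to a donor, culture or day, and there are 2 pairs only. The main fit therefore has no term for the number, values are printed per number, and the fit with that term is an alternative. The alternatives were other pseudocounts, low-value filters, scalings, limma without a trend, the replicate number as a term, each library left out in turn and other thresholds, and, chosen after seeing the data, limma-voom on the reads and combinations with the number as a term. Negative binomial count models that had been planned were not run, because too few low values were there to check the reads that the steps give. Peaks were summarised in Python 3.11.15 with pandas 2.3.3, and starts were raised by 1 so that positions count from 1. Positions of genes in hg19 and the genome sequence were not used here, so the planned comparisons of peaks with promoters of changed genes, of fold changes of bound genes and of the EGR1 motif in peaks were not made. Peaks off the autosomes enter totals only.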

Results

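The RNA data comprised 4 libraries from CD34+ haematopoietic stem and progenitor cells (HSPCs, the immature blood-forming cells) that had been isolated from human cord blood and expanded in a mix of haematopoietic cytokines (stem cell factor, thrombopoietin, FLT3 ligand and the interleukins IL-3 and IL-6). Cells carried a short hairpin RNA against EGR1 (shEGR1, 2 libraries, replicate numbers 1 and 2) or the control hairpin labelled Ren (shRen, 2 libraries, replicate numbers 1 and 2), and were sorted for GFP 4 days after transduction. EGR1 is a zinc-finger transcription factor of the immediate early class. The table held 12677 genes in library-scaled read counts (CPM), and the reads in these genes, read back from the CPM steps, were 39.94 M and 42.09 M for shEGR1 numbers 1 and 2, and 42.05 M and 41.47 M for shRen numbers 1 and 2. A second assay, chromatin immunoprecipitation with an antibody to EGR1 (ChIP-seq) in the same cell type, had 3 ChIP samples and 1 input sample, and was represented by a single list of 32753 peaks. The labels do not say whether the replicate numbers mark separate donors, cultures or days, so p-values measure the spread between these libraries only, which may be technical.

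EGR1 itself was lower with the EGR1 hairpin at both replicate numbers, the direction that the labels call for. FOSB, another immediate early gene and not the target, changed by −1.55 and −0.36 on the log2 scale at numbers 1 and 2. The fall of EGR1 therefore does not by itself tell a knockdown from a lower level of immediate early RNA. Its level was 23.2 CPM with shEGR1 against 76.8 CPM with shRen at number 1, and 396 CPM against 538 CPM at number 2. The log2 fold change on the log2(CPM + 1) scale was −1.68 at number 1 and −0.44 at number 2, and −1.06 over the 4 libraries. Because EGR1 differed more between numbers than between hairpins, the group means of 209 ± 263 CPM with shEGR1 (SD, n = 2) and 307 ± 326 CPM with shRen (SD, n = 2) overlapped, and limma gave an adjusted p of 1. With the replicate number as a term limma's adjusted p for EGR1 was 1.81e-80, and 0.124 when that fit had no intensity trend. In the fit with the trend the prior degrees of freedom were infinite. Its standard error of 0.054 for EGR1 thus came from the trend over all genes. The p-value of 1.81e-80 therefore does not measure how far the EGR1 change differed between the 2 numbers. The log2 fold change of EGR1 in the authors' deposited table was −1.08 with an FDR of 0.531. Leaving out shEGR1 number 1 turned the EGR1 value to 0.955, and leaving out shRen number 2 turned it to 0.333, since the remaining libraries were then unbalanced over the numbers. Each later fit that leaves out a library, for genes or lists, carries the difference between numbers in the same way. Its sign and calls therefore do not test the knockdown change.

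**Figure D1:**
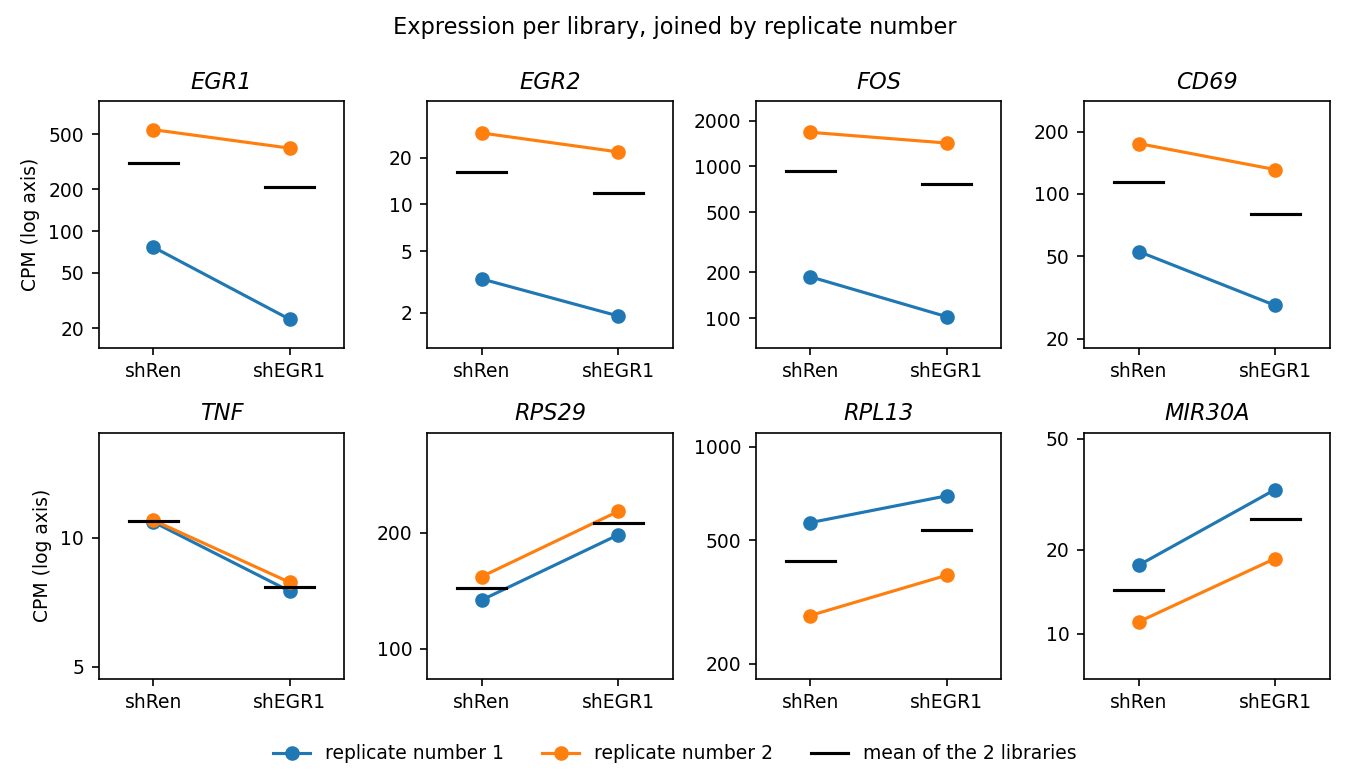
CPM on a log axis for 8 genes in each of the 4 libraries, with dots joined within replicate number 1 (blue) and number 2 (orange) and black bars at the mean of the 2 libraries of a group. EGR1, EGR2, FOS, CD69 and TNF lie lower and RPS29, RPL13 and MIR30A higher with shEGR1 at both numbers, while EGR1 ranges from 23.2 to 76.8 CPM at number 1 and from 396 to 538 CPM at number 2.

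The comparison of shEGR1 with shRen asks which transcripts depend on EGR1 in these cells. With shEGR1, 19 of 31 immediate early genes and 19 of 22 genes of NF-kB signalling and inflammatory cytokines had lower levels at both numbers, and 3 and 1 of them higher levels. Among ribosomal protein genes 45 of 46, and among nuclear genes of oxidative phosphorylation 30 of 33, had higher levels at both numbers. Of the genes tested here, 221 were called higher and 83 lower at an FDR under 0.05 in the authors' deposited table. limma on the 4 libraries, with the 2 libraries of each group as replicates, called 0 of 12639 genes at an adjusted p under 0.05. A single gene, RPS29, had an unadjusted p under 0.05 in limma. By limma-voom on the reads the count was 0 genes in the same layout and 282 with the replicate number as a term, and limma with the number as a term called 337, of which 249 were higher and 88 lower. With libraries centred on their median that last split was 219 higher and 167 lower. Without an intensity trend the fit with the number as a term called 5 genes, 3 higher and 2 lower.

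The libraries separated by replicate number, not by hairpin. Pearson's r across genes was 0.9977 between shEGR1 and shRen at number 1 and 0.9973 at number 2, against 0.922 between the 2 shEGR1 libraries and 0.92 between the 2 shRen libraries. The SD over genes of the log2 difference between numbers was 0.761, whereas the SD of the knockdown fold change was 0.133 within number 1 and 0.139 within number 2. Number 2 held less erythroid RNA, with a median log2 difference of −2.72 over 30 erythroid genes, and more RNA of immediate early genes, with a median of 1.09 over 31 genes. HBG2, a fetal globin gene, stood at 978 CPM in shRen number 1 and 10.1 CPM in shRen number 2. CD34 stood at 10.8 CPM in shRen number 1 and 51.7 CPM in shRen number 2. Over all genes the fold changes at number 1 and number 2 correlated with a Pearson r of 0.222 and a Spearman rho of 0.21 across genes, which are not independent replicates. Their signs were equal for 56.7% of genes. Changes of at least 0.3 on the log2 scale were upward at both numbers for 25 genes, where independent changes would give 5.42, and downward at both for 16 genes, where they would give 4.13. Groups did not overlap for 597 genes, 4.72% of those tested. Chance would give 33.3% for 2 against 2 if the 4 libraries were interchangeable. That share does not apply here, because the difference between numbers exceeded the knockdown change and keeps most groups overlapping.

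**Figure D2:**
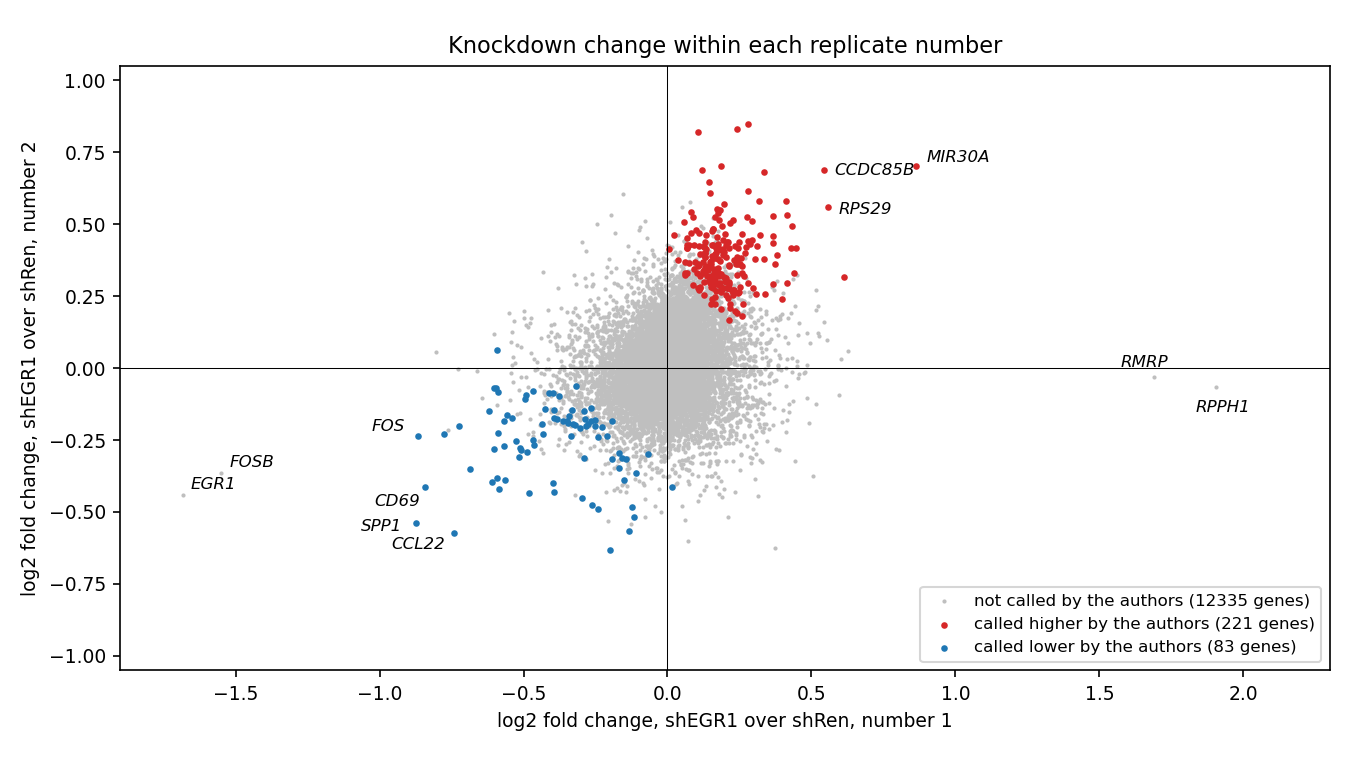
Log2 fold change of shEGR1 over shRen on the log2(CPM + 1) scale within replicate number 1 (x axis) and number 2 (y axis), 1 dot per gene, with the 221 genes called higher in the authors' deposited table in red, the 83 called lower in blue and the others in grey. EGR1 lies at −1.68 and −0.44, and MIR30A at 0.86 and 0.70, while RPPH1 and RMRP lie far right of 0 and close to 0 on the y axis.

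The genes with the smallest p among those whose groups did not overlap were named by a fixed rule, and none of these 24 passed limma at the adjusted threshold. RPS29, a ribosomal protein gene, stood at 197 and 227 CPM with shEGR1 and at 134 and 154 CPM with shRen, a log2 difference of 0.56 at both numbers. MIR30A, a microRNA gene, stood at 32.8 and 18.6 CPM against 17.6 and 11.1 CPM, with log2 differences of 0.86 and 0.70. TNF, the inflammatory cytokine, stood at 7.50 and 7.87 CPM against 10.9 and 11.0 CPM, with log2 differences of −0.48 and −0.43. In the authors' deposited table RPS29 rose by 0.56 (FDR 1.66e-19), MIR30A rose by 0.83 (FDR 7.53e-17) and TNF changed by −0.51 (FDR 0.0014). The same table also called HINT1 (0.34), MIF (0.32), PRSS57 (0.35), VAMP8 (0.23), SNHG6 (0.32), RABAC1 (0.27), A1BG (0.56), MDP1 (0.40) and GNG11 (0.30) higher, with log2 fold changes in parentheses. MIF is a cytokine and PRSS57 a serine protease of azurophil granules. The ribosomal protein genes RPS23 (0.26), RPS20 (0.24) and RPS13 (0.19) were called higher in the authors' deposited table as well. It called CD274 (−0.49), which encodes the checkpoint ligand PD-L1, TDRD6 (−0.67), RASGEF1B (−0.54) and TCN1 (−0.37), a vitamin B12 binding protein of granulocytes, lower. The remaining 5 of the 24 missed the threshold there, with log2 fold changes in the authors' deposited table of 0.47 for TNNT1, 0.49 for HIST1H2BH, −0.25 for REPS2, −0.40 for PLBD1 and 0.33 for KLRG1.

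Lists of genes fixed before the data were examined were called in both directions, more of them lower than higher. camera with a preset correlation of 0.01 called 10 of the 31 lists with at least 5 tested members, 3 higher and 7 lower with shEGR1. With a correlation estimated from the 4 libraries 0 lists were called (smallest adjusted p = 0.72), and by fry 0 (smallest adjusted p = 0.99). Both the estimate and the camera test that uses it rest on 2 residual degrees of freedom. That leaves the test little power, so its lack of calls neither backs nor speaks against the calls at the preset correlation. The estimated correlation was −0.018 for the mast cell and −0.0378 for the TGF-beta list, under the preset 0.01, and their calls ended all the same. Within the lists limma called 0 members, over all genes tested and also adjusted over the list alone.

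The EGR family and the NAB corepressors, which bind EGR proteins, had 5 tested members. EGR2 stood at 1.91 and 21.8 CPM with shEGR1 against 3.31 and 28.8 CPM with shRen, and EGR3 at 0.571 and 5.95 CPM against 0.804 and 9.78 CPM. In the authors' deposited table EGR2 fell by 0.49 on the log2 scale (FDR 0.00123) and EGR3 fell by 0.68 (FDR 0.00592). The NAB1 log2 fold change was −0.02 and that of NAB2 −0.04 in the authors' deposited table, neither past the threshold. The list's median was −0.42 and camera's adjusted p was 0.096, or 8.22e-05 with the replicate number as a term and 0.771 with that term and an estimated correlation. The median was 0.656 without shEGR1 number 1 (camera, adjusted p = 0.0104), −1.49 without shEGR1 number 2 (adjusted p = 3.41e-06), −1.71 without shRen number 1 (adjusted p = 0.000101) and 0.333 without shRen number 2 (adjusted p = 0.0245). EGR3, NAB1 and NAB2 were chosen after their values were seen. Among 13 genes that textbooks name as EGR1 targets, the authors' deposited table called SERPINE1, the plasminogen activator inhibitor, lower (−0.46), and ICAM1 had −0.17 without passing. That list had a median of −0.03 and an adjusted p of 0.233 in camera.

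Immediate early genes other than EGR were lower as a list, with a median log2 fold change of −0.16 over 31 genes, −0.16 at number 1 and −0.15 at number 2 (camera, adjusted p = 0.00396, and adjusted p = 0.764 with an estimated correlation). Of the 31, 19 were lower and 3 higher at both numbers, and 9 were called lower in the authors' deposited table. FOS, a subunit of the AP-1 transcription factor, stood at 102 and 1424 CPM with shEGR1 against 187 and 1676 CPM with shRen. In the authors' deposited table FOS fell by 0.54 on the log2 scale (FDR 6.61e-11), SGK1 fell by 0.36 (FDR 4.42e-06) and DUSP1, a phosphatase of MAP kinases, fell by 0.33 (FDR 6.89e-06). FOSB stood at 4.84 CPM against 16.1 CPM at number 1 and 644 CPM against 830 CPM at number 2, and did not pass in the authors' deposited table (log2 fold change −1.04, FDR 0.594). The list also differed between numbers, with a median 1.09 higher in number 2. Its median turned to 0.379 without shEGR1 number 1 (camera, adjusted p = 6.07e-06) and 0.427 without shRen number 2 (camera, adjusted p = 0.000261), and was −0.681 without shEGR1 number 2 and −0.708 without shRen number 1.

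Genes of NF-kB signalling and inflammatory cytokines had a median of −0.18 over 22 genes, −0.21 at number 1 and −0.13 at number 2 (camera, adjusted p = 9.74e-12, and adjusted p = 0.764 with an estimated correlation). At both numbers 19 of the 22 were lower and 1 was higher. Called lower in the authors' deposited table were 5 of them, namely PTGS2 (−0.49), the inducible cyclooxygenase, the chemokine genes CCL3 (−0.51) and IL8 (−0.38), TNF (−0.51), and TNFAIP3 (−0.23), a feedback inhibitor of NF-kB that falls outside the naming rule. The list of cytokine receptors and signalling feedback genes had a median of −0.09 over 24 genes (camera, adjusted p = 0.0359, and adjusted p = 0.764 with an estimated correlation). This call ended under quantile normalization (adjusted p = 0.0521) and under median centring (adjusted p = 0.061). Its members CD69, an early activation antigen, SOCS3, a feedback inhibitor of cytokine signalling, and DUSP6 were called lower in the authors' deposited table, by log2 fold changes of −0.61, −0.31 and −0.22. SOCS1 had 0.21 there and did not pass. The TGF-beta pathway list had a median of −0.06 over 18 genes (camera, adjusted p = 0.00396, and adjusted p = 0.718 with an estimated correlation). SERPINE1 (−0.46) and TGFBI (−0.25) were called lower in the authors' deposited table, while SKIL (−0.33) and SMAD6 (0.18) did not pass. Without shEGR1 number 1 and without shRen number 2 the medians were 0.104 and 0.0587 for the NF-kB list and 0.181 and 0.144 for the receptor and feedback list, none past camera's threshold. Without shEGR1 number 2 and without shRen number 1 they were −0.325 and −0.296 for the NF-kB list and −0.275 and −0.234 for the receptor and feedback list, all past it. The TGF-beta call ended whichever library was left out, with medians of −0.0918 and −0.00976 without shEGR1 numbers 1 and 2, and −0.045 and −0.063 without shRen numbers 1 and 2.

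For 3 lists of mature myeloid markers, camera's direction at the preset correlation was down, with medians that differed between the 2 numbers, a difference that was not tested. Monocyte, macrophage and dendritic cell genes had a median of −0.16 over 29 genes (camera, adjusted p = 1.14e-07, and adjusted p = 0.718 with an estimated correlation), and of −0.26 at number 1 against −0.02 at number 2. Of the 29, 4 were called lower in the authors' deposited table, namely TLR2 (−0.29), a sensor of bacterial lipoproteins, and VCAN (−0.26), MS4A7 (−0.27) and CLEC7A (−0.24), the last 3 named after their values were seen. MRC1 (−0.42), FCN1 (−0.30) and CD163 (−0.26) did not pass in the authors' deposited table. Neutrophil granule and granulocyte genes had a median of −0.02 and a mean of −0.05 over 25 genes (camera, adjusted p = 0.0116, and adjusted p = 0.764 with an estimated correlation), with −0.21 at number 1 and 0.02 at number 2, and 6 of the 25 were lower at both numbers. RNASE2, a granule ribonuclease, was the single member called in the authors' deposited table (−0.24), and DEFA4 (−0.32), MMP9 (−0.24) and RNASE3 (−0.18) did not pass. Mast cell, basophil and eosinophil genes had a median of −0.14 over 20 genes (camera, adjusted p = 2.94e-06, and adjusted p = 0.718 with an estimated correlation), with −0.05 at number 1 and −0.17 at number 2. The eosinophil granule genes EPX and PRG3 both fell by 0.26 on the log2 scale in the authors' deposited table, and IL5RA (−0.27) and SIGLEC8 (−0.26) did not pass. Left out in the order shEGR1 numbers 1 and 2, then shRen numbers 1 and 2, the libraries gave medians of 0.162, −0.431, −0.383 and 0.127 for the monocyte list, past camera's threshold in the middle 2 fits. The same order gave 0.175, −0.307, −0.121 and −0.0962 for the neutrophil list, past it without shEGR1 number 2 only, and −0.253, −0.0505, −0.0833 and −0.217 for the mast cell list, past it in the first and last fits.

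Cytosolic ribosomal protein genes were higher, with a median of 0.17 over 46 genes (camera, adjusted p = 2.92e-23, and adjusted p = 0.764 with an estimated correlation), 0.10 at number 1 and 0.21 at number 2. At both numbers 45 of the 46 were higher, and 18 were called higher in the authors' deposited table, among them RPL13 (0.36), RPL35 (0.33), RPS19 (0.31) and RPL37 (0.28). Reads of ribosomal protein genes can be shared with their many pseudogenes, so their levels are uncertain to that extent. Nuclear genes of oxidative phosphorylation (OXPHOS) had a median of 0.12 over 33 genes (camera, adjusted p = 4.86e-08, and adjusted p = 0.764 with an estimated correlation), 0.06 at number 1 and 0.17 at number 2. Of the 33, 30 were higher at both numbers and 7 were called higher in the authors' deposited table, among them UQCRQ (0.34), COX5B (0.31), COX6C (0.29) and NDUFA2 (0.26), subunits of complexes III, IV and I. MYC targets and ribosome biogenesis genes had a median of 0.06 over 30 genes (camera, adjusted p = 0.0252, and adjusted p = 0.764 with an estimated correlation), with 0.00287 at number 1 and 0.13 at number 2. SRM, the spermidine synthase, was the single member called in the authors' deposited table (0.19), and BOP1 (0.22), PPAN (0.18) and MRTO4 (0.15) did not pass. Both the ribosomal protein and the OXPHOS lists were lower in number 2 than in number 1, by median log2 differences of −0.43 and −0.55. The direction of these lists was the same under quantile normalization and median centring. Leaving out a library unbalances the numbers, so the difference between numbers enters the medians, and their sign does not test the knockdown change. Without shRen number 2 the medians were −0.0665 for the ribosomal protein, −0.16 for the OXPHOS and −0.244 for the MYC list. Without shEGR1 number 1 they were −0.0207, −0.0797 and −0.141. In the same order of lists they were 0.347, 0.356 and 0.343 without shEGR1 number 2, and 0.409, 0.422 and 0.398 without shRen number 1.

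**Figure D3:**
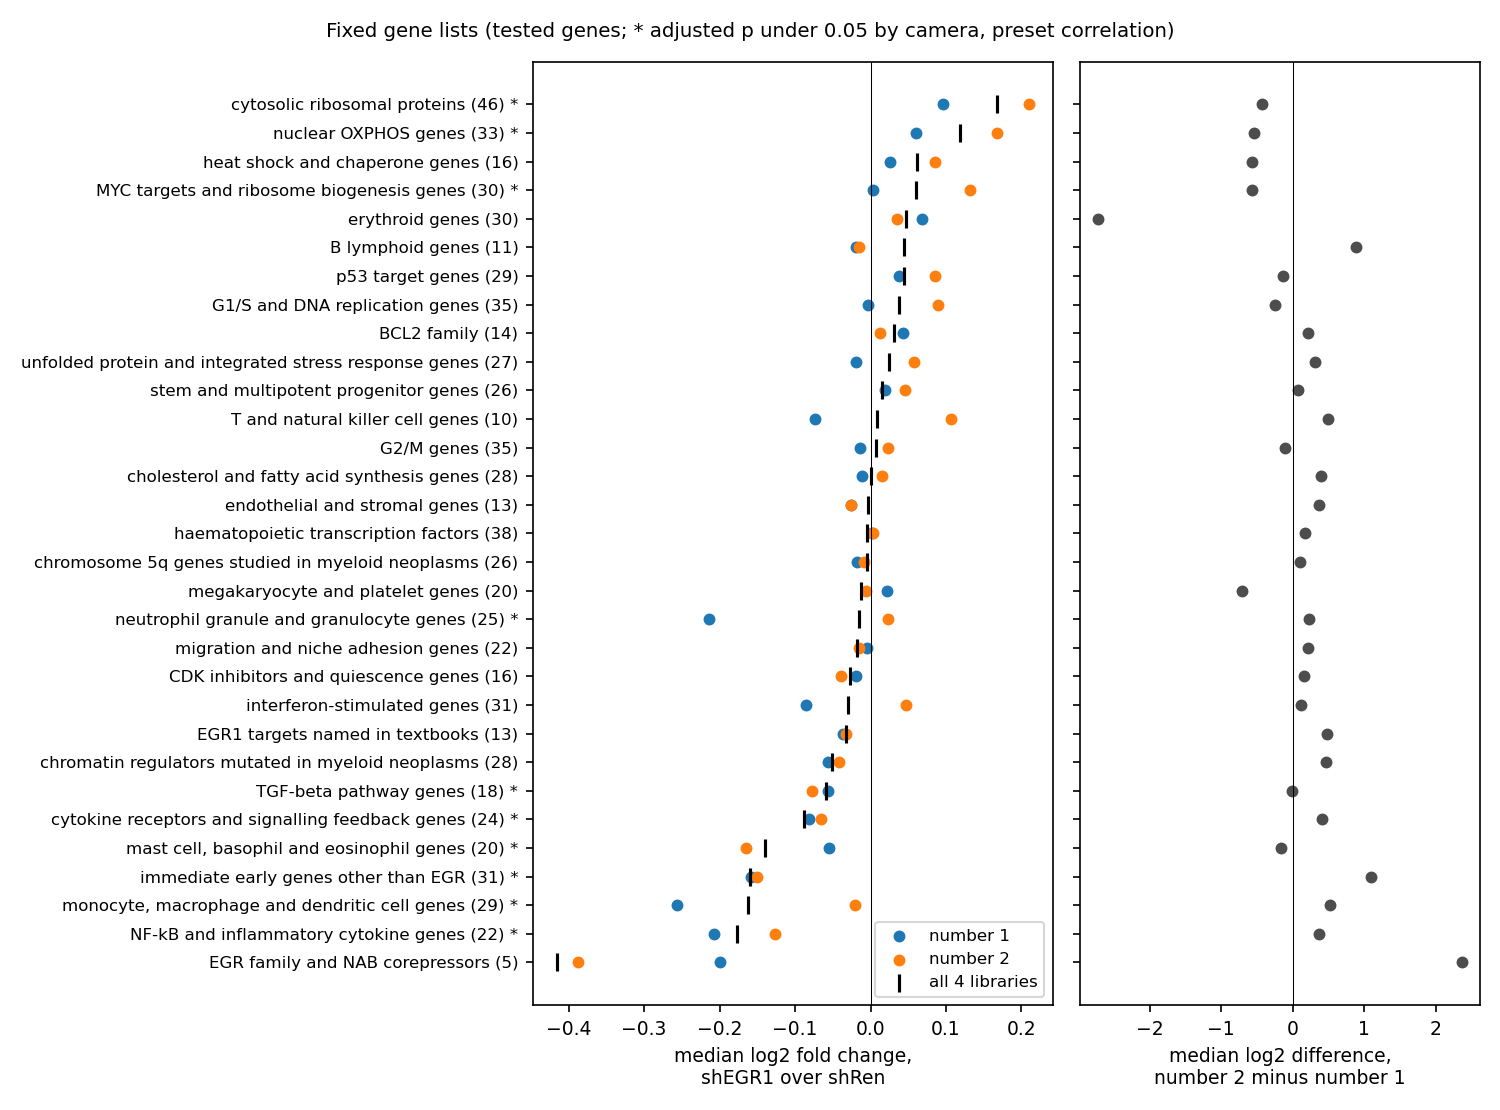
Median log2 fold change of shEGR1 over shRen for 31 gene lists (left panel) at number 1 (blue), number 2 (orange) and over the 4 libraries (black tick), and the median log2 difference of number 2 minus number 1 for the same lists (right panel). Tested members are in parentheses and an asterisk marks an adjusted p under 0.05 by camera with the preset correlation. The ribosomal protein list is highest at 0.17 and the EGR list lowest at −0.42, and the monocyte list lies at −0.26 at number 1 and −0.02 at number 2.

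The other lists did not pass camera in the fit without a term for the replicate number. In limma with that term camera passed 3 of them, namely erythroid genes (adjusted p = 0.0215), chromatin regulators (adjusted p = 0.0164) and the EGR family list, each with an adjusted p of 0.771 at an estimated correlation. In limma-voom with that term it passed these 3 and also EGR1 targets named in textbooks (adjusted p = 0.0207), G1/S genes (adjusted p = 0.0194), heat shock genes (adjusted p = 0.0322) and chromosome 5q genes (adjusted p = 0.0258). Erythroid genes had a median of 0.05 over 30 genes (adjusted p = 0.923), and in the authors' deposited table the globin genes HBG2 (0.32), HBD (0.25) and HBB (0.22) were called higher, whereas HBE1 (0.23) did not pass. HBD and HBB were named after their values were seen. Globin genes are near-identical copies in part, so reads can be split between them. Stem and multipotent progenitor genes had a median of 0.02 over 26 genes (adjusted p = 0.407), with SPINK2 (0.49) and PROM1 (0.38), which encodes CD133, called higher in the authors' deposited table. CD34, named after its value was seen, had 0.20 there without passing. Among 11 B lymphoid genes (median 0.04, adjusted p = 0.547) the authors' deposited table called IGLL1, a surrogate light chain gene, higher (0.38) and gave −0.24 for BLNK. Megakaryocyte and platelet genes had a median of −0.01 (adjusted p = 0.547), with 0.21 for both MPL and PF4 in the authors' deposited table. T and natural killer cell genes had a median of 0.01 (adjusted p = 0.914), with 0.56 for CD3E and 0.32 for TCF7 in the authors' deposited table. Endothelial and stromal genes had a median of −0.00389 (adjusted p = 0.547), with COL6A1 called lower (−0.38) and TAGLN at 0.27 in the authors' deposited table. In the list of haematopoietic transcription factors (median −0.00464, adjusted p = 0.917), LYL1 was called higher (0.23) in the authors' deposited table, and KLF4 had −0.21. The median and the mean differed in sign for 3 of these lists, with means of −0.0058 for the B lymphoid, 0.00324 for the megakaryocyte and 0.00474 for the transcription factor list, and camera's direction was down in each. Left out in the order shEGR1 numbers 1 and 2, then shRen numbers 1 and 2, the libraries gave medians of −1.32, 1.42, 1.41 and −1.3 for the erythroid and −0.379, 0.388, 0.348 and −0.321 for the megakaryocyte list, all past camera's threshold.

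Cell cycle lists had medians near 0 over the 4 libraries. The median of G1/S and DNA replication genes was 0.04 (adjusted p = 0.132), with 0.16 for CDT1 and 0.15 for GINS2 in the authors' deposited table, and that of G2/M genes was 0.00746 (adjusted p = 0.923), with 0.15 for CENPA and 0.11 for UBE2C. CDK inhibitors and quiescence genes had a median of −0.03 (adjusted p = 0.39), with BTG2, an antiproliferative gene, called lower (−0.24) and CDKN1C at 0.27 in the authors' deposited table. In the p53 target list (median 0.04, adjusted p = 0.584) the authors' deposited table called FDXR higher (0.22, named after its value was seen) and BTG2 lower (−0.24), and gave 0.22 for PHLDA3. The BCL2 family had a median of 0.03 (adjusted p = 0.547), with 0.21 for BBC3 and 0.20 for BAD in the authors' deposited table. Interferon-stimulated genes had a median of −0.03 (adjusted p = 0.324), with ISG15 called higher (0.46) and IFIT2 at −0.23 in the authors' deposited table. Heat shock and chaperone genes had a median of 0.06 (adjusted p = 0.31), with 0.16 for HSPB1 and 0.13 for HSPE1 in the authors' deposited table. Unfolded protein and integrated stress response genes had a median of 0.02 (adjusted p = 0.324), with SDF2L1 called higher (0.33) and VLDLR lower (−0.34) in the authors' deposited table. Cholesterol and fatty acid synthesis genes had a median of 0.00107 (adjusted p = 0.547), with 0.16 for MVD and 0.15 for FDPS in the authors' deposited table. Migration and niche adhesion genes had a median of −0.02 (adjusted p = 0.278), with −0.17 for ICAM1 and −0.16 for CXCR4 in the authors' deposited table. Chromatin regulators mutated in myeloid neoplasms had a median of −0.05 (adjusted p = 0.114), with −0.17 for TET2 and −0.13 for EP300 in the authors' deposited table. Genes of chromosome 5q studied in myeloid neoplasms, the region that holds EGR1, had a median of −0.00509 over 26 genes (adjusted p = 0.547), with −0.26 for TIFAB in the authors' deposited table. With shEGR1 numbers 1 and 2 and then shRen numbers 1 and 2 left out in turn, the medians were −0.204, 0.317, 0.363 and −0.242 for heat shock genes and 0.208, −0.285, −0.252 and 0.19 for chromatin regulators, all past camera's threshold. Without shEGR1 number 1 and without shRen number 2 camera also called the unfolded protein list (0.207 and 0.212) and the cholesterol list (0.193 and 0.181), and without shRen number 1 the G1/S list (0.136). None of the 15 mitochondrially encoded genes of the fixed lists was in the table, so that list was not analysed here.

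The ChIP-seq assay asks where EGR1 sits on the genome of these cells. The deposited list held 32753 peaks in hg19 coordinates, which together covered 12.2 Mb, and all peak names referred to ChIP sample 3 against input, so the list gives no measure of agreement between the 3 ChIP samples. Scores, fold values and q-values are the authors' own. Most peaks were weak, with a median fold over input of 3.56 (quartiles 3.12 and 4.07, range 1.88 to 36.8) and a median −log10 q of 3.6. A fold of at least 5 was reached by 2698 peaks (8.24%), of at least 10 by 552 (1.69%) and of at least 20 by 83 (0.253%). Peak width ranged from 157 to 2650 bp with a median of 296 bp. Wider peaks were stronger, with a median width of 239 bp in the lowest and 451 bp in the highest of 4 equal bins of fold (Spearman rho 0.401 over peaks, which are not independent replicates).

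The peak with the highest score lay on chromosome 17 from 49230640 to 49231114 (hg19), with its summit at 49230890 and a fold of 27.8. Next in score came chromosome 10 from 104473908 to 104474518 (fold 35.8), chromosome 12 from 57482260 to 57483923 (fold 34.7) and chromosome 7 from 156685636 to 156686514 (fold 35.2). They were followed by chromosome 2 from 191878610 to 191879262 (fold 28.0) and chromosome 10 from 69644052 to 69644749 (fold 36.8, the highest fold of the list). The last 4 of the 10 highest scores were chromosome 16 from 28833732 to 28835105 (fold 35.6), chromosome 5 from 150826949 to 150827823 (fold 33.6), chromosome 9 from 131709158 to 131710163 (fold 28.6) and chromosome 2 from 191513180 to 191514483 (fold 31.2). An annotation in hg19 was not used here, so the genes at these peaks are not named. Peaks were densest on chromosome 19, with 50.0 per Mb between its outermost summits, followed by chromosome 22 with 42.9 per Mb and chromosome 17 with 31.7 per Mb, and sparsest among the autosomes on chromosome 13 with 4.47 per Mb. Summits were clustered. The median distance between neighbouring summits on the autosomes was 8870 bp, and 18.2% of neighbouring summits lay within 1000 bp of each other. The same numbers of summits placed at random along each autosome gave 1.76% within 1000 bp, as the mean of 100 placements. Placement was uniform between the outermost summits, including stretches where no peak could be called. Any unevenness along a chromosome thus adds to the difference, and what the summits cluster around was not tested.

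**Figure D4:**
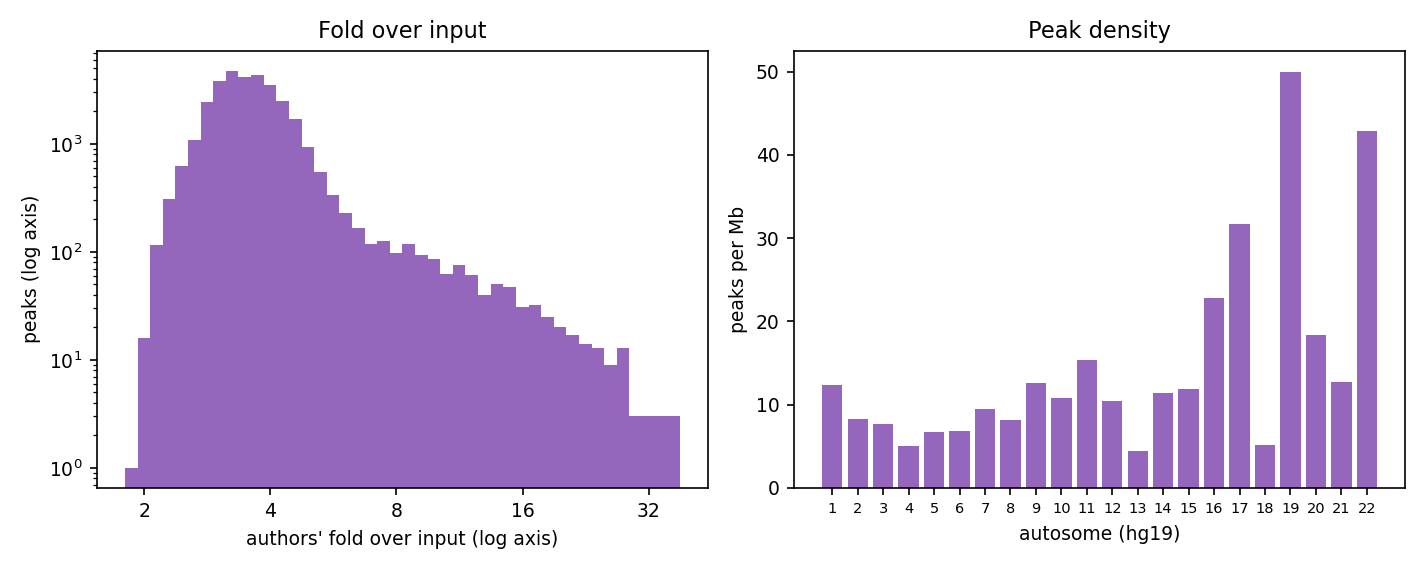
Left, number of peaks (log axis) by the authors' fold of ChIP over input (log axis) for all 32753 peaks. Right, peaks per Mb between the outermost summits of each autosome in hg19, with bars starting at 0. The bulk of peaks lies near the median fold of 3.56 with a tail up to 36.8, and density runs from 4.47 per Mb on chromosome 13 to 50.0 per Mb on chromosome 19.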

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

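Tests chosen only after the data were seen are limma-voom, the combinations of the replicate number as a term with other settings, and the values within a number. The EGR1 log2 fold change was negative under each pseudocount, filter and scaling (−1.09 to −1). The count of 0 called genes was the same under each pseudocount, scaling, limma without a trend, a mean of at least 5 CPM, an adjusted p under 0.10 and a minimum fold. In the simulation no gene was recovered without a term for the number, so this says nothing about stability. The setting with no low-value filter removed or added no gene and is void. The camera count of 10 lists was 9 under quantile normalization and median centring, and 0 with an estimated correlation or by fry. With an estimated correlation camera's test rests on 2 residual degrees of freedom, which leaves it little power. A higher correlation does not explain the loss for the mast cell and TGF-beta lists, whose estimates of −0.018 and −0.0378 lay under the preset 0.01. Whether the correlation added to the loss for other lists, and why fry called none, was not tested. Median fold over input was 4.03 for the 17185 peaks in the upper part of the score and 3.56 for all peaks. All peaks lay on the main chromosomes, so that setting changed nothing. The planned negative binomial count models were not run, nor were the alternatives for promoter peaks and the motif, which need hg19 genes or sequence not used here. Depth limits genes under 5 CPM most, where the median counting error of a log2 ratio within a number was 0.187, against a median absolute log2 fold change of 0.26 among genes called with the replicate block.

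Same-numbered libraries deviated together, with a correlation of 0.975 between their deviations from the group means, and the first principal component, with 97.3% of the variance, separated the numbers. No label says what the numbers mark, so this is a hint from the data and not from the design. With the replicate block, limma called 337 genes (249 higher, 88 lower), of which 287 were also called in the authors' deposited table, which comes from the same 4 libraries and so is no independent support. The replicate block left EGR1 at −1.06, now past the threshold (adjusted p = 1.81e-80). It leaves 1 residual degree of freedom per gene and pools the spread over all genes, and when the block was fitted without a trend, 5 genes passed, namely SPP1 (−0.706), CCL22 (−0.657), CCDC85B (0.615), MIR30A (0.782) and RPS29 (0.557), with an adjusted p of 0.124 for EGR1. limma-voom with the block called 282 genes, of which 257 were shared with limma, and put EGR1 at −0.98 past the threshold. With quantile normalization the block gave 354 genes and EGR1 at −1.09, and with median centring 386 genes (219 higher, 167 lower) and EGR1 at −1.08, both past the threshold. Lists called under the block were 13 with limma and 17 with limma-voom. With an estimated correlation, on 1 residual degree of freedom, limma's block called 0 (smallest adjusted p = 0.77), and this was not run for limma-voom. The 3 lists that limma's block added were erythroid genes, chromatin regulators and the EGR family, and limma-voom's block added these, EGR1 targets named in textbooks, G1/S, heat shock and chromosome 5q genes. The median of the 337 absolute log2 fold changes was 0.26, 334 had the same sign at both numbers, and 1 exceeded 2-fold. Named genes kept their sign in all alternatives except those that leave out a library and the values within a number. Within number 1 the sign turned for PPAN (−0.015), UBE2C (−0.031), NAB1 (0.04) and NAB2 (0.012), and within number 2 for TAGLN (−0.036), RPPH1 (−0.067) and RMRP (−0.033).

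Leaving out 1 library sets 1 library against 2, with the lone library assumed to vary like the others, and unbalances the numbers, so the difference between numbers enters the fold change. No gene was called in any of these fits, but camera called 10 lists without shEGR1 number 1, 13 without shEGR1 number 2, 13 without shRen number 1 and 11 without shRen number 2. The erythroid, EGR family, heat shock, megakaryocyte and chromatin regulator lists, not called with all 4 libraries, were called in each of these fits, with directions that turned, and the report gives their medians and those of the 10 lists called with all 4. The EGR1 value ran from −3.08 to 0.955, and 76 named genes changed sign, most of them without shEGR1 number 1 (63 genes) or without shRen number 2 (62 genes). Among immediate early and EGR genes the values ran from −1.96 to 1.01 for EGR2, from −1.71 to 0.873 for EGR3, from −0.356 to 0.329 for NAB1, from −0.341 to 0.272 for NAB2, from −2.44 to 1.34 for FOS, from −4.35 to 2.44 for FOSB, from −1.88 to 1.16 for DUSP1, from −1.0 to 0.272 for SGK1 and from −2.2 to 1.69 for KLF4. Among cytokine and feedback genes the values ran from −1.78 to 0.773 for PTGS2, from −1.35 to 0.344 for CCL3, from −1.52 to 0.741 for IL8, from −0.968 to 0.521 for TNFAIP3, from −1.79 to 0.476 for CCL22, from −2.36 to 0.944 for SPP1, from −1.7 to 0.442 for CD69, from −0.314 to 0.695 for SOCS1, from −1.28 to 0.61 for SOCS3, from −0.779 to 0.339 for DUSP6, from −0.538 to 0.208 for CXCR4 and from −0.555 to 0.203 for ICAM1. Among TGF-beta and stromal genes the values ran from −1.11 to 0.362 for SERPINE1, from −0.543 to 0.0608 for TGFBI, from −0.588 to 0.895 for SMAD6, from −0.997 to 0.229 for COL6A1 and from −0.149 to 0.568 for TAGLN. Among monocyte and eosinophil genes the values ran from −0.788 to 0.143 for MRC1, from −1.1 to 0.498 for TLR2, from −0.964 to 0.402 for CD163, from −1.61 to 1.08 for VCAN, from −0.82 to 0.284 for MS4A7, from −0.847 to 0.363 for CLEC7A and from −1.0 to 0.494 for PRG3. Among progenitor and lymphoid genes the values ran from −0.887 to 1.27 for CD34, from −0.196 to 0.984 for SPINK2, from −0.954 to 1.52 for PROM1, from −0.563 to 1.03 for LYL1, from −0.51 to 1.23 for IGLL1, from −0.908 to 0.448 for BLNK, from −0.338 to 0.948 for CD3E and from −0.0432 to 0.486 for TCF7. Among erythroid and platelet genes the values ran from −2.83 to 3.63 for HBG2, from −2.61 to 3.08 for HBB, from −1.66 to 2.17 for HBD, from −1.66 to 2.31 for HBE1 and from −1.71 to 2.07 for PF4. Among ribosomal, respiratory chain and biogenesis genes the values ran from −0.138 to 0.854 for RPL13, from −0.000483 to 0.667 for RPL35, from −0.0834 to 0.77 for UQCRQ, from −0.253 to 0.884 for COX5B, from −0.279 to 0.806 for NDUFA2, from −0.383 to 0.783 for BOP1, from −0.334 to 0.717 for SRM, from −0.329 to 0.697 for PPAN and from −0.257 to 0.557 for MRTO4. Among cell cycle, p53 and survival genes the values ran from −0.327 to 0.64 for CDT1, from −0.15 to 0.443 for GINS2, from −0.1 to 0.389 for CENPA, from −0.249 to 0.472 for UBE2C, from −0.0257 to 0.527 for CDKN1C, from −0.402 to 0.852 for PHLDA3, from −0.444 to 0.879 for FDXR, from −0.479 to 0.877 for BBC3 and from −0.159 to 0.554 for BAD. Among the remaining genes the values ran from −0.329 to 1.56 for CCDC85B, from −0.651 to 0.395 for EP300, from −0.518 to 0.837 for HSPB1, from −0.632 to 0.905 for HSPE1, from −0.0021 to 0.317 for MVD, from −0.242 to 1.31 for MZT2B, from −0.477 to 2.13 for RMRP, from −0.656 to 2.49 for RPPH1, from −0.0217 to 0.681 for SDF2L1, from −0.832 to 0.501 for TET2, from −0.769 to 0.243 for TIFAB and from −1.9 to 1.3 for VLDLR.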

Other observations

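Outside the fixed lists, several genes moved at both numbers and were chosen after their values were seen. SPP1 (osteopontin) stood at 4.87 and 56.8 CPM with shEGR1 against 9.76 and 82.8 CPM with shRen, and the chemokine gene CCL22 at 5.56 and 30.6 CPM against 9.98 and 45.9 CPM. In the authors' deposited table SPP1 fell by 0.67 on the log2 scale (FDR 2.71e-14) and CCL22 fell by 0.67 (FDR 1.06e-10). CCDC85B and MZT2B, the latter a subunit of the gamma-tubulin complex, were higher, with 70.4 and 20.3 CPM against 47.9 and 12.2 CPM and with 107 and 54.1 CPM against 90.2 and 30.1 CPM. The authors' deposited table gave CCDC85B 0.62 (FDR 4.01e-14) and MZT2B 0.53 (FDR 2.01e-06).

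RPPH1 and RMRP, the RNA parts of RNase P and RNase MRP, were higher at number 1 alone. RPPH1 stood at 26.4 CPM with shEGR1 against 6.31 CPM with shRen at number 1, and at 2.09 against 2.23 CPM at number 2. RMRP stood at 19.3 against 5.30 CPM at number 1 and at 2.33 against 2.40 CPM at number 2. No test compared the 2 numbers for these genes.

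The tests in the next paragraphs that were chosen only after the result was seen are those on RNA without a poly(A) tail, on scaling, on macrophage genes at number 2 and on lists matched along the axis between numbers.

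Ribosomal protein and OXPHOS genes were higher with shEGR1 at both numbers. Both lists stayed past camera's threshold under quantile normalization and median centring, with a smallest median of 0.0973. A factor common to all genes cannot set a list apart from other genes, so it cannot have made these calls. The median of all genes shifted by at most 0.0204 under these scalings, which is less than either list's median. These values argue against scaling of the libraries as the source of the rise of these 2 lists over other genes. These calls hold at the preset correlation only. With an estimated correlation, at which camera called 0 of the 31 lists, the adjusted p was 0.764 for both lists before any rescaling. That test had little power, on 2 residual degrees of freedom. A gain of reads in short transcripts stays open. The 17 genes of small OXPHOS subunits had a median of 0.189 and the 9 genes of large subunits 0.0785. The difference was 0.11 (permutation test with 100000 resamples, p = 0.0115). The median of all genes was 0.00313, so the large subunits were higher too but less so. In the MYC and ribosome biogenesis list, genes of small proteins lay 0.0676 above those of large proteins (same permutation test, p = 0.051). The test permutes genes as if independent, so its p does not measure the spread between libraries. Carry-over of RNA without a poly(A) tail cannot be told apart from the hairpin's effect, because 4 of 29 listed RNAs were measured, of which 0 were higher at both numbers. All 4 were higher at number 1, by 1.90 for RPPH1, 1.69 for RMRP, 0.23 for SCARNA12 and 0.02 for SCARNA9. At number 2 all 4 were slightly lower, from −0.01 for SCARNA12 to −0.11 for SCARNA9. An effect of EGR1 on these genes is a hypothesis that the design names, untested beyond the comparison itself.

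Immediate early, cytokine and monocyte genes had medians below 0 with shEGR1 over the 4 libraries. These calls hold at the preset correlation only, with adjusted p = 0.764, 0.764 and 0.718 in camera at an estimated correlation. That test had little power, on 2 residual degrees of freedom. Without shEGR1 number 1 the medians turned to 0.379, 0.104 and 0.162, where the difference between numbers enters the fold change. Within numbers the medians were below 0, at −0.159, −0.207 and −0.256 in number 1 and −0.15, −0.127 and −0.0206 in number 2. Fewer macrophages in the shEGR1 libraries may contribute at number 1, where all 11 macrophage restricted genes with at least 5 CPM were lower (median −0.344), among them CD14, CD163, C1QA and CSF1R. Their spread, 2.4 times the counting error at number 1, does not decide this, since the bound of 2 set beforehand compares single libraries with counting error alone, which variation between libraries exceeds as well. At number 2 the macrophage genes had a median of −0.0182 and the 51 immediate early and cytokine genes −0.15, a difference of 0.132 (permutation test with 100000 resamples, p = 0.0397). That does not exclude macrophages there, since 7 of the 11 were lower, 4 of them by as much as the −0.15, and the test permutes genes between 1 library of each group. Across genes the knockdown change went with the difference between numbers (Pearson r = −0.456, and −0.332 and −0.38 within numbers 1 and 2). A shift of the shEGR1 cells along the axis that separates the numbers would give this, but the lists followed it in part only. Erythroid genes, with a median of −2.72 between numbers, changed by 0.0471, and ribosomal protein genes, with −0.425, by 0.168. Mast cell genes, with −0.169, fell by 0.14, while immediate early genes, with 1.09, fell by 0.16. A random list matched on that axis had a median as low as the −0.163 of the 81 list genes in 0 of 10000 draws (lowest −0.0734). Position on the axis alone stays open all the same, because the draws treat genes as independent and the 3 lists were picked from 31 by their calls. An effect of EGR1 on these genes stays open as a hypothesis.

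MIR30A was higher with shEGR1 at both numbers, by 0.86 and 0.70. Vectors for short hairpins often use a miR-30 backbone, and the labels do not say whether these did, so reads from the vector could account for the value if the 2 vectors were expressed unequally. Of the other microRNA genes, MIR142 alone had a mean of at least 5 CPM, and 0 of these passed limma with the replicate number as a term. With a single such gene a vector source cannot be told apart from a change of MIR30A itself.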
